A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

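Poly(A)-enriched RNA of 9 yeast samples (3 unfrozen, 3 frozen for 24 h, 3 frozen for 48 h) was measured on Affymetrix Yeast Genome 2.0 arrays, per the labels. The deposited values are an intensity per probe set on a linear scale, which the submitters' processing notes credit to GCOS (version not given in the sources used here). The sample descriptions name GeneSpring 7.3.1, scaling of each chip to the 50th percentile and division of each gene by the unfrozen samples, but the deposited values have different medians on each array and no per-gene ratio, so these steps are not seen in them. The array holds probe sets for budding and fission yeast. Of its probe sets, 5498 were listed with 1 S. cerevisiae gene, 1746 with a S. pombe gene, 1 with several genes, 166 were controls and 3517 were not listed with a gene. Gene symbols came from the platform's annotation, updated through gene identifiers to the RefSeq table of assembly R64. No coordinates were used, since the files name no genome build.

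Values were taken to log2 and each array was set to the same median over S. cerevisiae probe sets. Probe sets were tested if their mean scaled log2 value was above 2.21, the 95th percentile of S. pombe probe sets (4.64 on the linear scale), and the probe set with the highest mean stood for its gene, which left 5396 genes. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (group means over all 9 arrays, empirical Bayes moderation with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Differences are on the log2 scale, positive where the first-named or frozen group is higher, with standard errors from this fit, and SD values are between arrays. Because at most 3 arrays form a group, single measures such as the rRNA signal were compared with exact two-sided permutation tests. Where the lower of the group means compared lay under the background threshold, a difference is given as at least that between the other mean and the threshold. Gene lists were tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), again with an estimated correlation, under which no list fixed before the data were examined passed in any comparison, and with fry. Neither form of fry compares a list with other genes.

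The gene lists, the design, the named-gene rule and most alternatives were fixed before the data were examined. The lists covered copper uptake and buffering, the iron and zinc regulons, heat shock, oxidative and general stress, trehalose and glycogen, ribosome biogenesis and ribosomal proteins, the proteasome, the unfolded protein response, cell wall integrity, ergosterol and fatty acid synthesis, cold-induced genes, aquaporins, amino acid synthesis, glycolysis, respiration, glucose-repressed genes, histones, mating-type genes and sporulation. Some lists share members, so their results are not separate findings. In another list as well were 13 of 37 general stress, 9 of 23 trehalose, glycogen and glycerol, and 5 of 13 cold-induced genes. Named for 24 h and 48 h against unfrozen are the 10 genes that rose most and the 10 that fell most among those past the threshold with non-overlapping arrays, all measured copper genes, and for each list past camera the 2 members with the smallest p in its direction. For the other comparisons 5 genes each way are named, or the 5 with the smallest p where none passed. Alternatives were quantile normalization, values as deposited, scaling to the median of all probe sets, a pseudocount of 1.65, no filter or one at the 99th percentile of background, no trend, only the groups compared, the replicate block, the mean of a gene's probe sets, a 2-fold minimum, and leaving out each array or replicate number. After the data were seen, 4 were added: the rRNA signal as a covariate, replicate 3 as a batch, the 2 brightest frozen arrays left out, and a replicate block on the frozen arrays alone.

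No 2 arrays shared more than 0.00915% of identical values, and all 9 columns were used. The procedure was tested on simulated data with 50 of 5396 genes changed at each of 4 fold sizes between frozen 24 h and unfrozen, in 20 runs. It recovered 15.4% of genes changed 1.5-fold, 50.9% of those changed 2-fold, 89.7% of those changed 4-fold and 97.1% of those changed 8-fold, and 5.11% of calls were false. A simulated 30-gene list shifted by 0.5 was called by camera in 20 of 20 runs and an unshifted list in 0. Genes were drawn independently in these runs, so neither the list results nor the 5.11% of false calls cover genes that vary together. In the data the estimated correlation was 0.861 among ribosomal protein genes and 0.31 among heat shock chaperones. Replicate numbers paired the 24 h and 48 h arrays, judged from the data alone, since deviations from the group means correlated at 0.59, 0.39 and 0.79 for the 3 numbers. Simulations of unchanged groups with errors so correlated were added after the data were seen. Arrays of the same group correlated at 0.898 to 0.988 and arrays of different groups at 0.910 to 0.991.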

Results

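The series addresses how budding yeast responds to freezing and thawing, with copper homeostasis named in its title. Log-phase cells of BY4741, a laboratory strain of Saccharomyces cerevisiae, were washed and held in distilled water. Cells were left unfrozen, or were kept frozen at -30 °C over 24 h or over 48 h and then thawed in a water bath for 10 min. Poly(A)-enriched RNA was measured on 9 single-colour Affymetrix arrays, 3 in each group. The labels speak of triplicates done independently and also of 2 independent experiments, so p-values measure the spread between these arrays, which may be partly technical. The median deposited signal of S. cerevisiae probe sets ranged from 201 in unfrozen replicate 2 to 726 in frozen 48 h replicate 3, and was 679 in frozen 24 h replicate 3. Between 97.4% and 98.7% of these probe sets per array lay above the 95th percentile of the S. pombe probe sets. The latter serve as background, since no fission yeast RNA was applied. The number of arrays limits the precision of the values.

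Loci deleted in BY4741 gave low signals. URA3, MET17 and LEU2 had mean scaled log2 signals of 0.68, 2.04 and 2.62, at percentiles 56.2, 92.7 and 97.8 of the background probe sets. HIS3 had a mean of 9.55, and its allele in this strain is a partial deletion, so it checks nothing here. Actin (ACT1) differed from unfrozen by -0.30 ± 0.42 at 24 h and -0.32 ± 0.42 at 48 h (SE, n = 3 arrays per group, limma adjusted p = 0.85 and 0.746), differences that turned to 0.12 and 0.20 under quantile normalization and to 0.11 at 48 h in the values as deposited. The 17 ribosomal RNA control probe sets had a median scaled log2 signal of 6.41 ± 0.84 (SD, n = 3) in unfrozen arrays, 9.35 ± 1.28 at 24 h and 9.07 ± 1.24 at 48 h. By this median each of the 6 frozen arrays lay above the 3 unfrozen ones. A two-sided exact permutation test gave p = 0.1 for each frozen group, the smallest that 3 arrays against 3 allow, and p = 0.0119 for both groups against unfrozen, the smallest that 84 splits allow. The latter treats the 6 frozen arrays as independent, although their numbers pair them, and over the 10 splits that part no pair p was 0.1.

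After 24 h frozen, HSP12, a small membrane-associated stress protein, was higher by 3.51 ± 0.31 on the log2 scale (SE, n = 3 per group, limma adjusted p = 0.00246). SPG4, a stationary-phase gene, rose by 4.16 ± 0.72 (adjusted p = 0.0251). YNL194C, which encodes a membrane protein, rose by 3.74 ± 0.45 (adjusted p = 0.0102). Rises were also found for the acetate transporter ADY2 (3.63 ± 0.68), the lactate permease JEN1 (3.29 ± 0.56), the carnitine transporter AGP2 (3.10 ± 0.33), the inositol phosphate synthase INO1 (2.78 ± 0.38) and the chaperone HSP82 (2.46 ± 0.43). POT1, the peroxisomal thiolase, and SMA1, a spore membrane gene, had unfrozen means of 1.93 and 1.88, under the background threshold of 2.21. Their rises were at least 3.58 and 2.56 on the log2 scale (adjusted p = 0.0121 and 0.0491). Among genes past the threshold, the largest falls were those of the cell wall sensor WSC4 (-2.48 ± 0.38), the seripauperin PAU4 (-1.86 ± 0.26), the mitotic cyclin CLB1 (-1.45 ± 0.18), the repressor NRG2 (-1.41 ± 0.25) and SFG1 (-1.37 ± 0.21). ICS2 (-1.20 ± 0.18), PAU18 (-1.17 ± 0.23), the sirtuin HST3 (-1.12 ± 0.17), the cell cycle inhibitor FAR1 (-1.04 ± 0.17) and the transcription factor SWI5 (-0.98 ± 0.19) followed. Adjusted p for these 10 falls ranged from 0.0111 to 0.0491. The probe sets of PAU4 and PAU18 are of a type that can bind related genes.

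In all, 54 of 5396 genes changed at 24 h, 43 higher and 11 lower, and 50 of them at least 2-fold. Frozen and unfrozen arrays did not overlap for 23.9% of genes, where chance gives 10%. Scaled to the median of all probe sets the split was 19 higher and 45 lower, and the count was 34 in the values as deposited and 139 with replicate 3 as a batch. With only the groups compared the count was 118. With rRNA signal as a covariate limma called 0 (139 at unadjusted p under 0.05, fewer than the share of 0.05 that chance gives). The count was 28 without replicate 1, 0 without replicate 2 (211 at unadjusted p under 0.05, also fewer) and 126 without replicate 3 in each group. Single arrays moved it too, to 4, 5 and 97 without unfrozen replicates 1, 2 and 3, to 22 and 10 without frozen 24 h replicates 2 and 3, and to 121, 34 and 93 without frozen 48 h replicates 1, 2 and 3.

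Chaperone genes under heat shock factor Hsf1 had a median of 0.52 at 24 h, with 5 of 26 higher and 10 adjusted over the list alone (camera adjusted p = 6.24e-12, adjusted p = 0.4 with an estimated correlation). The Hsp70 genes SSA4 (2.42 ± 0.29) and SSA1 (1.63 ± 0.23) were among these, with HSP82, and with HSP42 and BTN2, named after their values were seen. General stress genes under Msn2 and Msn4 also had a median of 0.52, with 5 of 37 higher and 15 adjusted over the list alone (camera adjusted p = 1.28e-09, adjusted p = 0.431 with an estimated correlation). They were HSP12, the catalase CTT1 (1.42 ± 0.20), the glycogen genes GPH1 and GLC3, and DCS2, named after its value was seen. Glucose-repressed and gluconeogenic genes had a median of 0.64, with 4 of 21 higher and 6 adjusted over the list alone (camera adjusted p = 1.55e-06, adjusted p = 0.236 with an estimated correlation). They were JEN1, ADY2, the regulator CAT8 (2.38 ± 0.40) and ADH2, the last named after its value was seen. Fry, which asks whether the genes of a list move one way on balance, gave adjusted p = 0.0428 for this list, 0.078 for heat shock, 0.144 for general stress and 0.493 for the trehalose and glycogen list. Scaled to the median of all probe sets, where the median of all genes moved to -0.34, the heat shock, general stress and glucose-repressed medians were 0.19, 0.19 and 0.31. In the values as deposited, where it moved to 0.28, they were 0.81, 0.81 and 0.93. In the trehalose, glycogen and glycerol list GPH1 (2.44 ± 0.46) and GLC3 (1.21 ± 0.19) were the 2 of 23 that were higher, with 4 adjusted over the list alone. Its median was -0.02 (0.02 under quantile normalization), its mean was 0.25 and camera pointed up (adjusted p = 0.0213, adjusted p = 0.599 with an estimated correlation). This list no longer passed without unfrozen replicate 3 (0.014), frozen 24 h replicate 2 (-0.13) or replicate 2 in each group (0.0042).

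Further lists passed camera upward at 24 h, each with a median that turned below 0 when arrays were scaled to the median of all probe sets. Oxidative stress genes had a median of 0.26 (-0.06 under that scaling), with CTT1 the 1 of 37 higher, also adjusted over the list alone, and OYE3 at 1.37 ± 0.40 (adjusted p = 0.558 with an estimated correlation). Proteasome genes had a median of 0.19 (-0.14), with 0 of 33 called, PRE1 at 0.55 ± 0.17 and RPN12 at 0.40 ± 0.16 (adjusted p = 0.558 with an estimated correlation). Iron regulon genes had a median of 0.30 (-0.03), with 0 of 25 called and 2 adjusted over the list alone, FRE4 at 1.16 ± 0.24 and HMX1 at 1.34 ± 0.32 (adjusted p = 0.663 with an estimated correlation). Sporulation genes had a median of 0.23 (-0.10), with 0 of 14 called, 2 higher and 1 lower adjusted over the list alone, NDT80 at 1.61 ± 0.34 and DIT1 at 0.81 ± 0.23 (adjusted p = 0.476 with an estimated correlation). Proteasome genes no longer passed camera scaled to the median of all probe sets (-0.14, adjusted p = 0.152), nor sporulation genes under quantile normalization (0.043, adjusted p = 0.536). By array the iron median was 0.82, 0.092 and 0.051 in frozen 24 h replicates 1, 2 and 3 and 0.47 in unfrozen replicate 3. The iron list no longer passed without frozen 24 h replicate 1 (0.028) or unfrozen replicate 1 or 2 (0.16 and 0.10), and without replicate 1 in each group its median was -0.094. Sporulation genes no longer passed without unfrozen replicate 1 (0.15), frozen 24 h replicate 1 (0.18), or replicate 1 (0.084) or 3 (0.30) in each group, nor proteasome genes without replicate 1 in each group (0.094).

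Fatty acid synthesis and desaturation genes had a median of -0.89 at 24 h, with 0 of 13 called and 7 lower adjusted over the list alone (camera adjusted p = 3.7e-06, adjusted p = 0.431 with an estimated correlation). The desaturase OLE1 stood at -2.50 ± 0.55 (adjusted p = 0.0673) and its activator MGA2 at -0.91 ± 0.25. Ergosterol genes had a median of -0.38, with 0 of 26 called, ERG28 at -0.90 ± 0.28 and ERG5 at -0.72 ± 0.20 (camera adjusted p = 3.85e-06, adjusted p = 0.558 with an estimated correlation). Cold-induced genes had a median of -0.48 with TIR1 at -2.54 ± 0.78 and OLE1 lowest in p, and HSP12 was the 1 of 13 higher (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.58 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.40, with 0 of 129 called, RPS0A at -0.57 ± 0.34 and RPL6B at -0.49 ± 0.29 (camera adjusted p = 2.98e-09, adjusted p = 0.599 with an estimated correlation). By array this median was -1.09 in frozen 24 h replicate 3, -0.15 in frozen 24 h replicate 1 and 0.05 in frozen 24 h replicate 2. Under quantile normalization it was -0.02 over all arrays and the list no longer passed camera (adjusted p = 0.415). Cold-induced genes had a median of -0.51 under that normalization and of -0.80 scaled to the median of all probe sets, but passed camera under neither (adjusted p = 0.0547 and 0.186). By array their median was -1.33 in frozen 24 h replicate 3, -0.21 in frozen 24 h replicate 1 and -0.36 in frozen 24 h replicate 2. They no longer passed without frozen 24 h replicate 3 (-0.22) or unfrozen replicate 2 (-0.37). The ergosterol median was -0.75 in frozen 24 h replicate 3, and -0.27 and -0.15 in frozen 24 h replicates 1 and 2.

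The core histone list, which also holds the linker histone gene HHO1, had a median of -0.44 at 24 h, with 0 of 9 called. HHT1 stood at -0.54 ± 0.32 and HHO1 at -0.44 ± 0.31. The list gave camera adjusted p = 0.00909, and adjusted p = 0.558 with an estimated correlation. Mating genes specific to a cells had a median of -0.30, with 0 of 7 called, ASG7 at -0.77 ± 0.30 and BAR1 at -0.28 ± 0.15 (camera adjusted p = 0.025, adjusted p = 0.558 with an estimated correlation). Amino acid synthesis genes had a median of -0.23, or 0.06 in the values as deposited, with 0 of 48 called, GDH1 at -0.995 ± 0.27 and BAT1 at -0.90 ± 0.27 (camera adjusted p = 0.0103, adjusted p = 0.7 with an estimated correlation). Camera was not passed at 24 h by ribosome biogenesis (median 0.07), the zinc regulon (-0.19), the unfolded protein response (0.06), cell wall integrity (0.02), aquaporins (-0.26), glycolysis (-0.36), nuclear-encoded respiration (-0.11), alpha-specific mating genes (0.12) or copper buffering (0.14). Under quantile normalization histones (-0.11), a-specific (-0.096) and amino acid synthesis genes (-0.071) no longer passed camera (adjusted p = 0.129, 0.294 and 0.131), nor did a-specific genes in the values as deposited (-0.0045, adjusted p = 0.0977). These 3 medians were -0.85, -0.70 and -0.49 in frozen 24 h replicate 3, and without that array (-0.21, -0.20 and -0.049) the lists no longer passed, nor did a-specific genes without unfrozen replicate 3 (-0.37). Leaving out a replicate number in each group ended these calls too, number 1 for histones (-0.36) and number 3 for a-specific (-0.22) and amino acid genes (-0.060). The sign of the 9 medians of the lists that did not pass turned under at least 1 other scaling. Some passed without 1 array, namely the zinc regulon without unfrozen replicate 3 (-0.26) or frozen 24 h replicate 1 (-0.24), cell wall integrity without frozen 24 h replicate 3 (0.30) and respiration without frozen 24 h replicate 2 (-0.26). Ribosome biogenesis did so without unfrozen replicate 1 (0.089) or 2 (0.076) or frozen 48 h replicate 1 (0.071). Without a replicate number in each group, the zinc (-0.35) and ribosome biogenesis lists (0.11) passed without 1, respiration (-0.29) without 2 and cell wall integrity (0.30) without 3. The zinc list had 2 genes lower adjusted over the list alone. The pyruvate kinase PYK2 (1.30 ± 0.20) and the NADH dehydrogenase NDE2 (2.36 ± 0.37), named after their values were seen, were the only members of these lists called.

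The copper uptake list, made of 6 targets of the copper-sensing activator Mac1 and MAC1 itself, had a median of 1.00 at 24 h. By limma 0 of 7 were higher over all genes tested, 3 adjusted over the list alone and 4 at unadjusted p under 0.05 (camera adjusted p = 0.000458, adjusted p = 0.476 with an estimated correlation). The copper transporter CTR1 stood at 1.87 ± 0.58 (adjusted p = 0.222), and the metalloreductases FRE1 at 1.89 ± 0.59 (adjusted p = 0.228) and FRE7 at 2.01 ± 0.68 (adjusted p = 0.271). REE1 stood at 1.00 ± 0.42, the transporter CTR3 at 0.74 ± 0.38, IRC7 at 0.66 ± 0.42 and MAC1 itself at -0.00 ± 0.14. REE1 and IRC7 are listed as Mac1 targets and are neither copper transporters nor metalloreductases, and the list median was the value of REE1. The CTR1 signal was 7.99 in both unfrozen replicates 1 and 2 and 10.62 in unfrozen replicate 3, within the 10.55 to 11.10 of the frozen arrays. In the values as deposited, where the median of all genes moved to 0.28, limma called CTR1 (2.17, adjusted p = 0.0294) and FRE1 (2.19, adjusted p = 0.0145). FRE7 (adjusted p = 0.0529) and CTR3 (adjusted p = 0.999) did not pass there. Without unfrozen replicate 3, CTR1 (2.75, adjusted p = 0.00126), FRE1 (2.78, adjusted p = 0.00308), FRE7 (2.80, adjusted p = 0.0432) and CTR3 (1.25, adjusted p = 0.0418) passed at 24 h. Without replicate 1 or 3 in each group the median of the list was 0.59 or 1.72 at 24 h. Over 25 alternatives adjusted p ranged from 0.0012, 0.00264, 0.0109 and 0.0418 for these genes up to 1 for each.

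Among 14 copper buffering and delivery genes limma called 0 at 24 h, also adjusted over the list alone, with 2 at unadjusted p under 0.05 (camera adjusted p = 0.794). The list's median of 0.14 turned to -0.19 when arrays were scaled to the median of all probe sets. The copper pump CCC2 stood at 0.75 ± 0.33, superoxide dismutase SOD1 at 0.12 ± 0.39, its chaperone CCS1 at -0.36 ± 0.17 and the chaperone ATX1 at 0.15 ± 0.30. The metallothionein CUP1-1, whose probe set can bind related genes, stood at -0.52 ± 0.41. Values for the others were COX23 0.44 ± 0.22, COX17 0.31 ± 0.35, CUP2 0.31 ± 0.17, SCO1 0.19 ± 0.32, CTR2 0.19 ± 0.51, COX19 0.06 ± 0.31, CRS5 -0.02 ± 0.32, SCO2 -0.29 ± 0.16 and COX11 -0.32 ± 0.14.

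**Figure D1:**
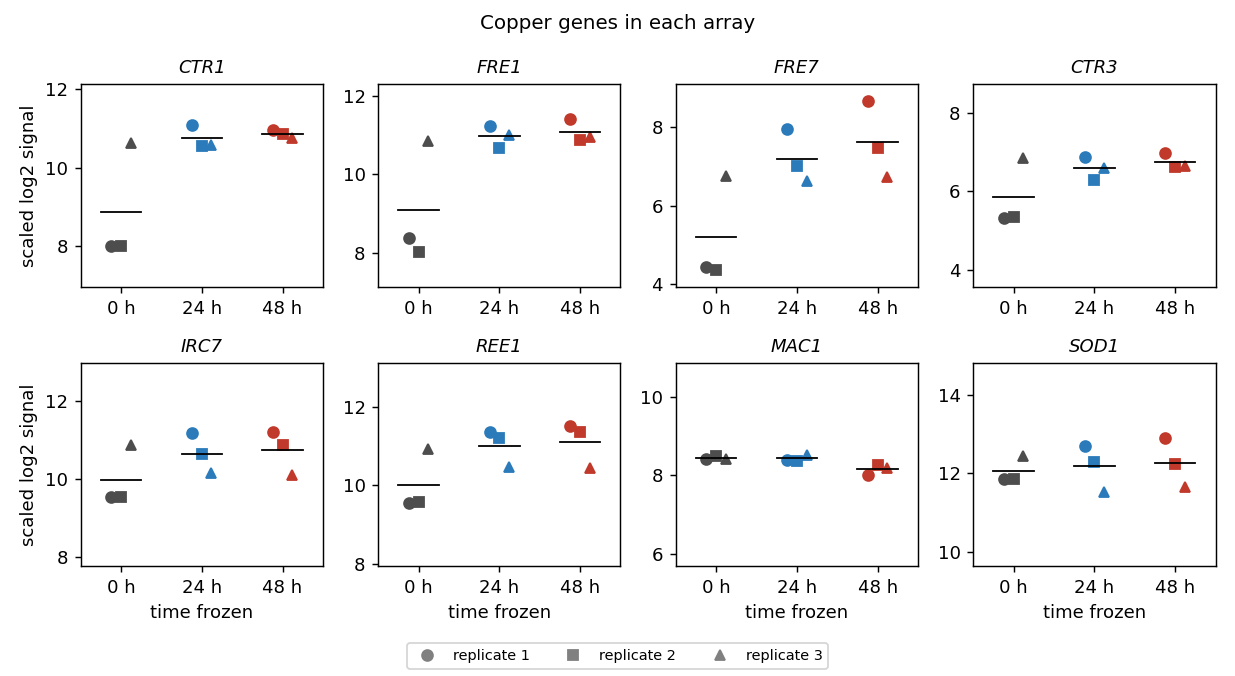
Scaled log2 signal of 8 copper genes in each array, by time frozen (0 h is unfrozen). Points are arrays, with 1 shape per replicate number, and horizontal lines are group means. For CTR1 the unfrozen arrays stand at 7.99, 7.99 and 10.62, and the frozen arrays between 10.55 and 11.10.

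After 48 h frozen, HSP12 was higher by 3.63 ± 0.31 (SE, n = 3 per group, limma adjusted p = 0.0018). YNL194C rose by 4.14 ± 0.45, AGP2 by 3.56 ± 0.33, INO1 by 3.37 ± 0.38 and JEN1 by 3.89 ± 0.56 (adjusted p from 0.00233 to 0.00638). ADY2 (3.93 ± 0.68), SPG4 (3.83 ± 0.72), GPH1 (2.84 ± 0.46) and the alcohol dehydrogenase ADH2 (2.82 ± 0.40) also rose, and POT1 rose by at least 3.79. Among genes past the threshold the largest falls were those of IZH4, a membrane protein linked to zinc and sterol metabolism (-3.40 ± 0.70), the phospholipase PLB2 (-2.72 ± 0.51), OLE1 (-2.69 ± 0.55), the haem synthesis gene HEM13 (-2.47 ± 0.54) and WSC4 (-2.36 ± 0.38). The sterol-binding protein gene HES1 (-2.32 ± 0.49), the hypoxic gene ANB1 (-2.26 ± 0.47), the repressors MIG2 (-1.95 ± 0.43) and NRG2 (-1.91 ± 0.25), and SFG1 (-1.85 ± 0.21) followed. Adjusted p for these 10 falls ranged from 0.00264 to 0.0424.

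In all, 157 of 5396 genes changed at 48 h, 113 higher and 44 lower, and 123 of them at least 2-fold. Frozen and unfrozen arrays did not overlap for 22.5% of genes, where chance gives 10%. The split was 57 higher and 208 lower scaled to the median of all probe sets, and 46 higher and 8 lower in the values as deposited, and the count was 237 with replicate 3 as a batch. With only the groups compared the count was 84. With rRNA signal as a covariate limma called 0 (252 at unadjusted p under 0.05, fewer than the share of 0.05 that chance gives). The count was 56 without replicate 1 and 0 without replicate 2 in each group (403 at unadjusted p under 0.05, more than that share). Without unfrozen replicates 1 and 2, frozen 24 h replicate 2 and frozen 48 h replicate 2, each in turn, it was 47, 44, 99 and 70.

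General stress genes had a median of 0.91 at 48 h, with 11 of 37 higher and 17 adjusted over the list alone (camera adjusted p = 5.86e-14, adjusted p = 0.255 with an estimated correlation). HSP12 and the glycogen branching enzyme GLC3 (1.65 ± 0.19) had the smallest p. Heat shock chaperones had a median of 0.75, with 7 of 26 higher and 15 adjusted over the list alone, including SSA4 (2.63 ± 0.29) and HSP42 (1.46 ± 0.18) (camera adjusted p = 1.6e-12, adjusted p = 0.255 with an estimated correlation). Glucose-repressed genes had a median of 0.74, with 6 of 21 higher and 9 adjusted over the list alone, including JEN1 and ADH2 (camera adjusted p = 1.64e-06, adjusted p = 0.238 with an estimated correlation). For these 3 lists fry gave adjusted p = 0.0194, 0.0194 and 0.0192, and 0.164 for the trehalose and glycogen list. Scaled to the median of all probe sets, where the median of all genes moved to -0.37, the 3 medians were 0.57, 0.41 and 0.40, and in the values as deposited, where it moved to 0.40, they were 1.33, 1.17 and 1.17. In the trehalose, glycogen and glycerol list 5 of 23 were higher and 6 adjusted over the list alone (median 0.42, camera adjusted p = 0.000157, adjusted p = 0.521 with an estimated correlation). They were GLC3, GPH1, the trehalase NTH1 (1.15 ± 0.17), and ATH1 and PGM2, named after their values were seen.

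Oxidative stress genes had a median of 0.24 at 48 h, or -0.10 scaled to the median of all probe sets, with CTT1 (1.75 ± 0.20) the 1 of 37 higher, 2 adjusted over the list alone and PRX1 at 0.77 ± 0.18 (camera adjusted p = 0.000556, adjusted p = 0.521 with an estimated correlation). Proteasome genes had a median of 0.22, or -0.12 under that scaling, with 0 of 33 called, PRE1 at 0.63 ± 0.17 and RPN12 at 0.49 ± 0.16 (camera adjusted p = 0.00128, adjusted p = 0.521 with an estimated correlation). Iron regulon genes had a median of 0.37, with FRE4 (1.39 ± 0.24) the 1 of 25 higher, 2 adjusted over the list alone and HMX1 at 1.28 ± 0.32 (camera adjusted p = 0.0304, adjusted p = 0.733 with an estimated correlation). OLE1 was the 1 of 13 fatty acid genes that fell, 5 adjusted over the list alone, with FAA4 at -1.64 ± 0.42 (median -0.78, camera adjusted p = 0.000157, adjusted p = 0.521 with an estimated correlation). Among 13 cold-induced genes OLE1 fell and HSP12 rose, 3 lower and 1 higher adjusted over the list alone, with TIR1 at -3.18 ± 0.78 (median -0.64, camera adjusted p = 0.0128, adjusted p = 0.521 with an estimated correlation). Ergosterol genes had a median of -0.39, or 0.04 in the values as deposited, with 0 of 26 called, 1 lower adjusted over the list alone, ERG5 at -0.85 ± 0.20 and ERG28 at -0.81 ± 0.28 (camera adjusted p = 0.000363, adjusted p = 0.618 with an estimated correlation). By array the iron median was 1.03, 0.19 and 0.065 in frozen 48 h replicates 1, 2 and 3. The iron list no longer passed without frozen 48 h replicate 1 (0.059) or unfrozen replicate 1 or 2 (0.18 and 0.17), and without replicate 1 or 2 in each group, where it failed too, its median was -0.022 or 0.22. The cold-induced median was -1.44 in frozen 48 h replicate 3, and -0.23 and -0.38 in frozen 48 h replicates 1 and 2. That of ergosterol genes was -0.79, -0.0065 and -0.30 in the same arrays. Without frozen 48 h replicate 3 neither list passed (-0.40 and -0.16).

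The core histone list had a median of -0.66 at 48 h, with 0 of 9 called. HHT1 stood at -0.82 ± 0.32 and the linker histone gene HHO1 at -0.71 ± 0.31. The list gave camera adjusted p = 0.00141, and adjusted p = 0.521 with an estimated correlation. Mating genes specific to a cells had a median of -0.36, or 0.06 in the values as deposited, with 0 of 7 called, BAR1 at -0.36 ± 0.15 and ASG7 at -0.50 ± 0.30 (camera adjusted p = 0.0432, adjusted p = 0.533 with an estimated correlation). Ribosomal protein genes had a median of -0.52, with 0 of 129 called, RPL22B at -0.58 ± 0.22 and RPS9A at -0.53 ± 0.20 (camera adjusted p = 1.58e-11, adjusted p = 0.618 with an estimated correlation). That median was -1.07 in frozen 48 h replicate 3, and -0.19 and -0.23 in frozen 48 h replicates 1 and 2. It was -0.04 under quantile normalization. Under that normalization a-specific genes no longer passed camera (-0.22, adjusted p = 0.098), nor in the values as deposited (adjusted p = 0.12). Scaled to the median of all probe sets, proteasome genes (-0.12, adjusted p = 0.0657) and cold-induced genes (-0.97, adjusted p = 0.0629) no longer passed. In frozen 48 h replicate 3 the histone and a-specific medians were -0.93 and -0.79. The a-specific list no longer passed without unfrozen replicate 2 (-0.33) or 3 (-0.32), frozen 24 h replicate 1 (-0.36), frozen 48 h replicate 2 (-0.41) or 3 (-0.11), or replicate 2 (-0.39) or 3 (-0.15) in each group.

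Camera was not passed at 48 h by sporulation genes (median 0.28, adjusted p = 0.11), amino acid synthesis (-0.22, adjusted p = 0.0981), ribosome biogenesis (-0.020, adjusted p = 0.866), the zinc regulon (-0.13, adjusted p = 0.158) or the unfolded protein response (0.15, adjusted p = 0.0767). Nor was it by cell wall integrity (0.23, adjusted p = 0.152), aquaporins (0.37, adjusted p = 0.866), glycolysis (-0.43, adjusted p = 0.387), respiration (-0.097, mean 0.00098, adjusted p = 0.57) or alpha-specific genes (0.47, adjusted p = 0.254). The sign of these medians turned under at least 1 other scaling, except those of aquaporins and alpha-specific genes. Under quantile normalization glycolysis passed camera upward (median 0.041, adjusted p = 0.0403). Named after their values were seen, the members called were NDT80 (1.58 ± 0.34), ERO1 (1.13 ± 0.22), KDX1 (1.11 ± 0.24), PYK2 (1.38 ± 0.20) and NDE2 (2.74 ± 0.37), which rose, and SPS4 (-1.34 ± 0.28), which fell. Adjusted over the list alone, 3 sporulation genes were higher and 1 lower, 2 zinc genes were lower and 2 cell wall integrity genes were higher. Without frozen 48 h replicate 1 the zinc (-0.22), amino acid (-0.39) and sporulation lists (0.35) passed, as did the unfolded protein response without frozen 48 h replicate 2 (0.15) and cell wall integrity without frozen 48 h replicate 3 (0.64). Without replicate 1 in each group the zinc (-0.32), amino acid (-0.39) and ribosome biogenesis lists (0.093) passed, and without replicate 3 cell wall integrity (0.61) and alpha-specific genes (1.13).

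Copper uptake genes had a median of 1.09 at 48 h, with 0 of 7 higher over all genes tested by limma, 4 adjusted over the list alone and 5 at unadjusted p under 0.05 (camera adjusted p = 0.00384, adjusted p = 0.521 with an estimated correlation). FRE7 stood at 2.44 ± 0.68 (adjusted p = 0.1), FRE1 at 2.01 ± 0.59 (adjusted p = 0.119) and CTR1 at 1.99 ± 0.58 (adjusted p = 0.117). REE1, whose value was again the list median, stood at 1.09 ± 0.42, CTR3 at 0.90 ± 0.38, IRC7 at 0.75 ± 0.42 and MAC1 at -0.28 ± 0.14. In the values as deposited, where the median of all genes moved to 0.40, limma called CTR1 (2.41, adjusted p = 0.00427), FRE1 (2.43, adjusted p = 0.0018) and FRE7 (2.86, adjusted p = 0.0018). CTR3 (adjusted p = 0.818) did not pass there. Without unfrozen replicate 3, CTR1 (2.86, adjusted p = 0.000896), FRE1 (2.89, adjusted p = 0.00218), FRE7 (3.22, adjusted p = 0.0175) and CTR3 (1.41, adjusted p = 0.0175) passed. Without replicate 1 in each group the list no longer passed camera at 48 h (median 0.65, adjusted p = 0.0586), and without replicate 3 its median was 1.88. Over 25 alternatives adjusted p ranged from 0.000782, 0.00104, 0.0018 and 0.0175 for these genes up to 1 for each. Copper buffering genes had a median of 0.11, or -0.23 scaled to the median of all probe sets, with 0 of 14 called by limma, also adjusted over the list alone, and 2 at unadjusted p under 0.05 (camera adjusted p = 0.903). CCC2 stood at 0.88 ± 0.33, SOD1 at 0.21 ± 0.39, CUP1-1 at -0.71 ± 0.41, CCS1 at -0.44 ± 0.17, ATX1 at -0.25 ± 0.30, COX23 at 0.40 ± 0.22 and COX19 at 0.38 ± 0.31. SCO1 stood at 0.33 ± 0.32, CUP2 at 0.20 ± 0.17, CRS5 at 0.12 ± 0.32, CTR2 at 0.10 ± 0.51, SCO2 at -0.14 ± 0.16, COX17 at -0.17 ± 0.35 and COX11 at -0.22 ± 0.14.

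**Figure D2:**
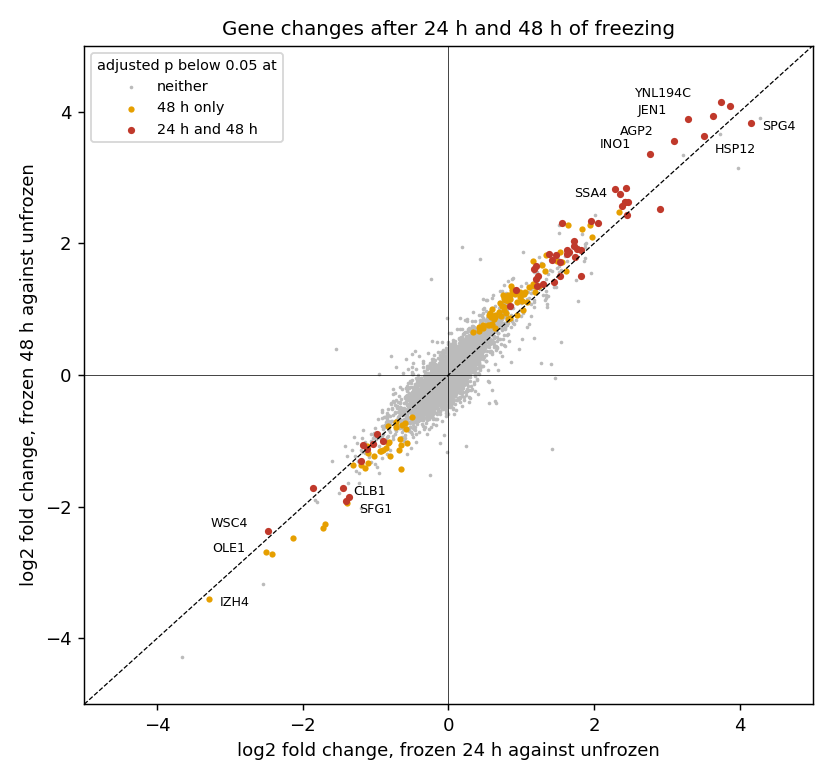
Log2 fold change of 5396 genes against unfrozen after 24 h (horizontal) and 48 h (vertical) of freezing. Each point is a gene, red where the adjusted p was under 0.05 at both times and orange at 48 h alone, and the dashed line marks equal changes. All 54 genes called at 24 h were also called at 48 h in the same direction.

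Between 48 h and 24 h frozen, limma called 0 of 5396 genes, and 22 had an unadjusted p under 0.05. With a replicate block on the frozen arrays it also called 0, and 135 had an unadjusted p under 0.05. Both counts lie below the share of 0.05 that chance alone gives among unchanged genes. The fit without a block leaves out the pairing by number, so its standard errors may be too large here. Its 0 calls thus do not show that the groups were alike. The genes with the smallest p and a positive difference were the aldo-keto reductase GCY1 (0.41 ± 0.13), ICP55 (0.47 ± 0.16), TRL1 (0.70 ± 0.26), LSB6 (0.63 ± 0.24) and TPO4 (0.83 ± 0.34). Those with a negative difference were LEU2, YGR035C (-0.77 ± 0.25), RBL2 (-0.50 ± 0.16), YJR151W-A (-1.08 ± 0.40) and AIM34 (-0.43 ± 0.18). Each had adjusted p = 1 (SE, n = 3 per group). LEU2 is deleted in this strain, and its 48 h mean of 1.40 lay under the background threshold of 2.21, so its 24 h mean of 3.94 was higher by at least 1.72. With 0 members called in each, 7 lists passed camera, namely general stress (median 0.33, adjusted p = 3.42e-10), trehalose and glycogen (0.29, adjusted p = 2.6e-06), heat shock (0.15), glucose-repressed (0.26), cell wall integrity (0.16), ribosome biogenesis (-0.08) and ribosomal proteins (-0.11). The last 2 medians turned to 0.05 and 0.02 in the values as deposited, and glucose-repressed genes no longer passed under quantile normalization (adjusted p = 0.0518). With an estimated correlation adjusted p was 0.738 or 0.988 for these lists. With a replicate block on the frozen arrays, cold-induced genes (-0.16, adjusted p = 0.00404) and the core histone list (-0.16, adjusted p = 0.00239) passed camera as well. Without a block each had adjusted p = 0.988 with an estimated correlation. Without replicate 1 in each group 1 list passed, and without replicate 2 glucose-repressed genes (0.20) and ribosomal proteins (-0.027) did not. Without frozen 48 h replicate 1, trehalose and glycogen (-0.013), heat shock (-0.0083), ribosome biogenesis (-0.029) and cell wall integrity (-0.11) no longer passed. Cell wall integrity also failed without frozen 24 h replicate 3 (-0.098) or frozen 48 h replicate 2 (0.097), and heat shock without frozen 24 h replicate 2 (0.079) or frozen 48 h replicate 3 (0.17). Ribosomal proteins failed without frozen 24 h replicate 1 (0.0035) or 2 (0.11) or frozen 48 h replicate 3 (0.17). Glucose-repressed genes failed without frozen 24 h replicate 1 (0.098) or frozen 48 h replicate 2 (0.15) or 3 (0.32). Lists outside these 7 passed when an array was left out. Without frozen 24 h replicate 1 these were iron (0.34), oxidative stress (0.14) and amino acid genes (0.11), and without frozen 24 h replicate 2 respiration (0.15), ergosterol (0.16) and amino acid genes (0.14). Without frozen 24 h replicate 3 they were glycolysis (-0.42), histones (-0.37), cold-induced (-0.49) and ergosterol genes (-0.13). Without frozen 48 h replicate 1 they were fatty acid (-0.25), cold-induced (-0.43), ergosterol (-0.17) and amino acid genes (-0.16). Histones (-0.37) passed without frozen 48 h replicate 2. Respiration (0.19), ergosterol (0.30) and amino acid genes (0.23) passed without frozen 48 h replicate 3, and respiration (0.14) without replicate 3 in each group.

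Both frozen groups as a whole differed from unfrozen in 198 of 5396 genes, 141 higher and 57 lower, and 125 of them at least 2-fold. This fit counts the 6 frozen arrays as independent although their numbers pair them, so its standard errors and p-values may be too small. SPG4 (3.996 ± 0.62), YNL194C (3.94 ± 0.39) and ADY2 (3.78 ± 0.59) rose (SE, n = 6 frozen and 3 unfrozen arrays, limma adjusted p = 0.0075, 0.0014 and 0.0075). POT1 and YLR012C, with unfrozen means of 1.93 and 0.42 under background, rose by at least 3.69 and 2.29. IZH4 (-3.35 ± 0.61), the cell wall mannoprotein gene TIR1 (-2.86 ± 0.67), OLE1 (-2.598 ± 0.47), PLB2 (-2.57 ± 0.44) and WSC4 (-2.42 ± 0.33) fell. Of the stress lists, 12 of 37 general stress genes, 8 of 26 heat shock chaperones and 6 of 21 glucose-repressed genes were higher, and 16, 15 and 9 adjusted over the list alone (adjusted p = 0.324, 0.324 and 0.229 with an estimated correlation). Copper uptake genes had a median of 1.04, with 0 of 7 called and 5 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.526 with an estimated correlation). That median was 0.62 without replicate 1 and 1.80 without replicate 3 in each group.

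For both groups against unfrozen, frozen and unfrozen arrays did not overlap for 13.9% of genes, where chance gives 2.38% for 6 independent arrays against 3, although the frozen arrays are paired by number. The split was 90 higher and 635 lower scaled to the median of all probe sets, and 66 higher and 9 lower in the values as deposited, and the count was 314 with replicate 3 as a batch. With rRNA signal as a covariate limma called 0 genes (217 at unadjusted p under 0.05, fewer than the share of 0.05 that chance gives). The count was 64 without replicate 1, 1 without replicate 2 and 302 without replicate 3 in each group. It was 64 and 51 without unfrozen replicates 1 and 2, 117, 125 and 121 without frozen 24 h replicates 1, 2 and 3, and 117 without frozen 48 h replicate 2.

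**Figure D3:**
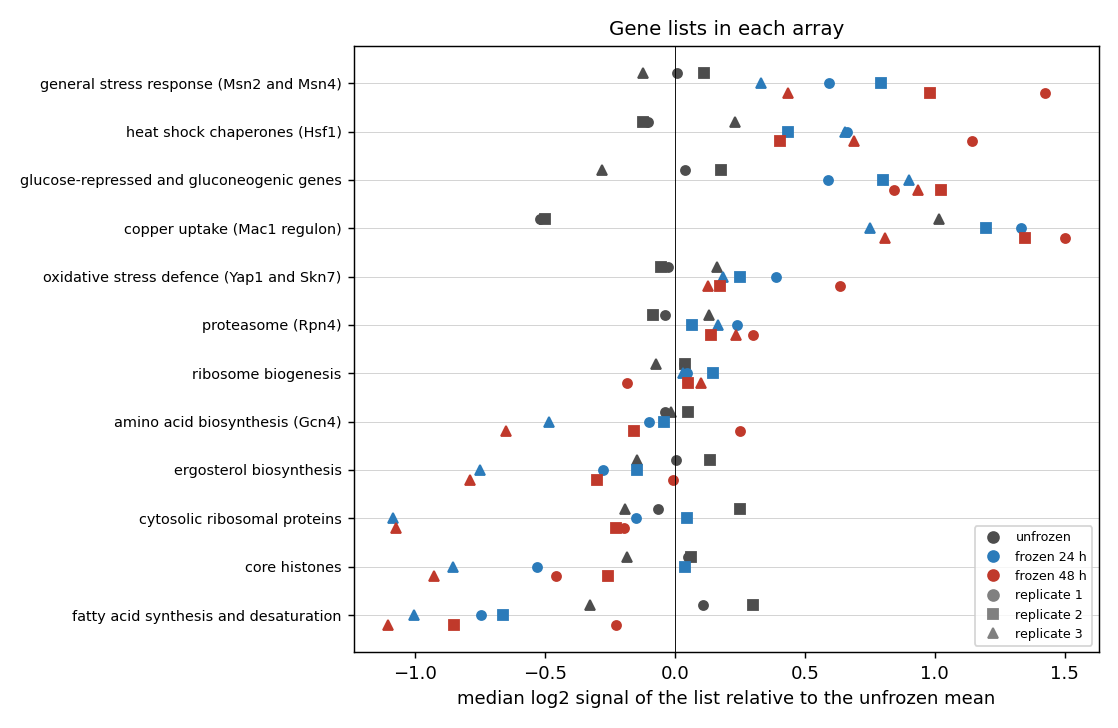
Median log2 signal of 12 gene lists in each array, relative to the mean of the unfrozen arrays. Colours are groups and shapes replicate numbers. Ribosomal protein medians stand at -1.09 and -1.07 in the frozen replicate 3 arrays and between -0.23 and 0.05 in the other frozen arrays, and copper uptake genes stand at 1.02 in unfrozen replicate 3.

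The changes at 24 h and 48 h were alike across genes, which are not independent replicates, with Pearson's r = 0.912 and Spearman's rho = 0.848. Unchanged groups simulated against the same 3 unfrozen arrays gave r = 0.501 with independent errors, because both comparisons share those controls. They gave a mean r of 0.794, and at most 0.818 in 100 runs, where errors of same-numbered frozen arrays were correlated as observed. Genes were drawn independently in these runs too, so the maximum does not cover genes that vary together. The covariance was 0.218 against 0.0688 with errors so correlated, a difference of 0.149. Changes had the same sign in 83.0% of genes, and in 79.2% of those so simulated. Of the genes called, 43 were higher at both times and 11 lower at both. Independent lists would share 0.900 and 0.0897, but both comparisons use the same 3 unfrozen arrays. The simulation with correlated errors gave means of 0 and 0.02. That was nearly fixed in advance, since unchanged groups yield almost no calls. Neither reference thus says how much of the overlap comes from the shared controls or the pairing. None was called in opposite directions. Part of the overlap may come from the shared controls, which were too few to split, and from the paired frozen arrays.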

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

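Of the tests in this part, those of array scaling or brightness for the copper and the rRNA signal, of copper genes within replicate 3, of called genes in proportion to rRNA signal and of splits that part no pair were chosen after the result was seen.

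Signal outside the tested genes differed between groups: the median of the 17 ribosomal RNA control probe sets was higher by 2.94 (log2) at 24 h and by 2.66 at 48 h than in the unfrozen arrays. Some single probe sets overlapped between the groups. For example, the 5' set of 18S rRNA stood at 9.85 in frozen 48 h replicate 2 and at 10.33 in unfrozen replicate 3. Among 429 probe sets above background with no listed gene, 8 were called between frozen and unfrozen arrays, 8 higher and 0 lower.

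Relative to the hybridization controls, which are added in fixed amounts, the rRNA rise was 3.48 (log2). A stronger sample signal would raise this measure as well, so it decides nothing about array brightness. With each array set to the same S. cerevisiae median, which takes out brightness shared by all probe sets, the rise was 2.80. Shared brightness as the whole source is thus argued against. Carry-over through the poly(A) selection that varied between arrays is not excluded: the planned exact permutation p over 84 splits was 0.0119, the smallest they can give, but it counts the 6 frozen arrays as independent although their numbers pair them, and over the 10 splits that part no pair p was 0.1. RNA processing that differed between the groups, and an effect of freezing itself, both stay open. As a source of the called genes rRNA is not excluded: as a covariate it ended all 198 calls between frozen and unfrozen arrays, with fold changes at a median of 0.891 of their former size and standard errors at 1.82 times theirs, because rRNA level follows the groups. The test planned for this named frozen 24 h replicate 1 as the array with the least rRNA. The called genes showed 0.899 of the mean change there, but that array is frozen 48 h replicate 2, so the test says nothing. A later test took genes called without each of these 2 arrays. Median shares were 0.789 (quartiles 0.649 and 1.01) and 0.998 against rRNA shares of 0.499 and 0.395. For the genes so called, this argues against changes in strict proportion to rRNA signal and leaves other forms open. The call favours genes that moved alike in the other frozen arrays, the partner by number among them, so other genes are not covered. The 3' to 5' signal ratios differed by -0.10 (log2) on average. By array they ran from 0.86 to 1.47 in frozen and from 1.23 to 1.33 in unfrozen arrays. They were lowest in frozen replicate 3 at 24 h (0.86) and 48 h (0.93).

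Copper uptake genes in unfrozen replicate 3 stood within the range of the frozen arrays, with a list median of 1.02 against 0.75 and 0.81 in the frozen replicate 3 arrays and at least 1.20 in the other frozen arrays. Scaling is argued against, since the median excess of the 6 Mac1 targets over unfrozen replicates 1 and 2 was at least 1.74 (log2) under each of 4 scalings. A frozen sample with a wrong label would lie near the frozen mean for other genes too, but over 170 genes called without this array it lay at a median of 0.40 of the way (quartiles 0.13 and 0.60). It thus stood between the groups for these genes. Over all genes it correlated at 0.977 and 0.976 with unfrozen replicates 1 and 2 and at 0.978 with frozen 24 h replicate 1. With the other frozen arrays it correlated at 0.933 to 0.971. A rise of these genes with freezing stays open, since the frozen minus unfrozen difference within replicate 3, -0.16, restates the pattern. Whether the numbers pair unfrozen with frozen arrays was also not settled by the data. A difference in the culture or its copper supply may account for the array, which was not tested, and 1 array cannot separate this from handling.

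Ribosomal protein genes had a median of -0.46 between frozen and unfrozen arrays, with 0 of 129 called (camera adjusted p = 2.68e-11, adjusted p = 0.589 with an estimated correlation), and frozen 24 h replicate 2 stood at 0.046, above the unfrozen mean. Compression of the brightest signals may account for most of it: the genes matched on mean signal, 20 per gene, had a median of -0.43, and the ribosomal protein genes differed from them by -0.0459 (95% bootstrap over genes -0.064 to -0.028). That interval takes the genes as independent and leaves out the spread between arrays. Without the 2 brightest frozen arrays the median was -0.13, between the limits set for and against those arrays as the whole source. Quantile normalization brought it to -0.03 (camera adjusted p = 0.0774), and no biological explanation was tested.

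Whether chance arrangements give as many genes was counted by fitting each split of the same arrays as 2 groups. For both frozen groups against unfrozen, the real split gave 246 genes. Since numbers pair the frozen arrays, it was compared with the 10 splits that part no pair, of which 1 gave as many genes and the highest other 3 (unfrozen replicate 3 with both frozen arrays of replicate 1), and 10 splits are too few for a share under 0.05. The 74 splits that part a pair gave at most 0. For 24 h the real split gave 118 and the highest other 0, for 48 h 84 and 0, and between 48 h and 24 h 0 and 0, with as many genes in 1, 1 and 10 of 10 splits, and 10 splits are too few for a share under 0.05.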

How the results depend on the processing

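Settings chosen after seeing the data were the rRNA covariate, replicate 3 as a batch, the 2 brightest frozen arrays left out and the block on the frozen arrays alone. Counts at 24 h, 48 h and for both frozen groups (54, 157 and 198) were 34, 54 and 75 in the values as deposited, where the median of all genes moved to 0.28, 0.40 and 0.33 (log2), 64, 265 and 725 scaled to the median of all probe sets, where it moved to -0.34, -0.37 and -0.36, and 0, 0 and 0 with the rRNA covariate, whose cause is discussed with the rRNA signal. With replicate 3 as a batch they were 139, 237 and 314, and with the groups compared alone 118 and 84, and the cause was not tested. A 2-fold minimum left 125 for both frozen groups. Unfrozen and frozen arrays deviated together for number 2 (0.25 at 24 h and 0.13 at 48 h). They did not for number 1 (-0.38 and -0.23) or number 3 (-0.12 and -0.07). Since 7 of 9 arrays correlated best with their own number, pairing of unfrozen with frozen arrays was neither shown nor excluded. The replicate block gave 113, 211 and 294, with the zinc regulon past camera at 24 h (adjusted p = 0.0321), and on the frozen arrays alone 0. Leaving out arrays or replicate numbers gave 0 to 126, 0 to 232 and 1 to 302, and 0 throughout for 48 h against 24 h, where no setting run called a gene. Lists past the threshold (16, 14, 7 for 48 h against 24 h, and 16) were 0 in each comparison with an estimated correlation, and 9 for both frozen groups with the rRNA covariate. Leaving out arrays gave 13 to 17, 12 to 16, 1 to 10 and 14 to 16. Of 62 named calls, 20 passed without any 1 array, 62 were lost without replicate 2 and 62 with the rRNA covariate, and 0 changed sign. The direction of camera reversed in some lists, given with their medians, and the cause was not tested. With the rRNA covariate these were, at 24 h, cold-induced genes (-0.022) and ribosomal proteins (0.16), and for both groups ribosomal proteins (0.084). Under quantile normalization they were glycolysis at 48 h (0.041) and for both groups (0.032). Leaving out arrays or numbers reversed the iron regulon at 24 h (range -0.094 to 0.72) and for both groups (-0.072 to 0.74), lowest without replicate 1. It reversed ribosome biogenesis at 48 h without replicate 1 (0.093, range -0.10 to 0.093). Between 48 h and 24 h it reversed cell wall integrity (-0.098 and -0.11, up to 0.47) and ergosterol genes (-0.13 and -0.17, up to 0.30) without frozen 24 h replicate 3 or frozen 48 h replicate 1. It also reversed amino acid synthesis without frozen 48 h replicate 1 (-0.16, up to 0.23), and ribosomal proteins without frozen 24 h replicate 2 (0.11) or frozen 48 h replicate 3 (0.17, range from -0.46). Signals near background limit genes such as POT1 to bounds.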

Other observations

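The lists and tests in this part were written after the changed genes were seen. Of 29 genes of the mitotic cyclin cluster, which are switched on together before cell division, 8 fell between frozen and unfrozen arrays (TEM1, HST3, CLB1, SWI5, CDC20, CDC5, CLB2 and HOF1), 27 lay below 0 and the median was -0.53 (camera adjusted p = 1.78e-13, adjusted p = 0.0124 with an estimated correlation). Because genes that showed the pattern led to the list, this p decides nothing. Over the 19 members whose values had not been seen, although the median of the whole list had, 17 lay below 0 with a median of -0.31 (camera adjusted p = 2.64e-05, adjusted p = 0.0279 with an estimated correlation), and 0 were called. With that median seen, at least 5 of the 19 had to lie at or below it, so this test was partly fixed in advance and decides nothing. Whether the cluster fell beyond the genes that led to the list stays open, since no other arrays were at hand to test it.

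Of 28 genes that respond to low oxygen, 10 fell between frozen and unfrozen arrays (OLE1, MGA2, COX5B, IZH4, AAC3, IZH1, HES1, TIR1, HEM13 and ANB1), 18 did not pass, and the median was -0.58 (camera adjusted p = 1.06e-07, adjusted p = 0.136 with an estimated correlation). This p decides nothing either, for the same reason. By array the median was -1.17 and -1.30 in the frozen replicate 3 arrays at 24 h and 48 h, -0.31 and -0.24 in those of replicate 1, -0.49 and -0.62 in those of replicate 2, and -0.20 in unfrozen replicate 3. Over the 13 members not seen before, 9 lay below 0 with a median of -0.24, and camera gave adjusted p = 0.157, which leaves open whether the list as a whole moved, since the members called are left out.

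LEU2 and MET17, both deleted in this strain, had scaled log2 signals of 3.59 and 2.38 in unfrozen replicate 1, 2.88 and 3.48 in unfrozen replicate 2 and 1.09 and 0.88 in unfrozen replicate 3. MET17 stood between 2.35 and 2.88 in the frozen 24 h arrays and between 0.91 and 1.44 in the frozen 48 h arrays. URA3, also deleted, stood between 0.71 and 1.24 at 24 h and at 1.52, -2.30 and 1.74 at 48 h. LEU2 stood between 3.69 and 4.19 in the frozen 24 h arrays and between 1.10 and 1.88 in the frozen 48 h arrays, and this difference did not pass the test over all genes (adjusted p = 1).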
